A study of Homo sapiens with 6 samples.

How the data were processed

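RNA was taken from MCF7-TAMR human breast cancer cells grown in RPMI1640 with 10% fetal bovine serum and 1 µM tamoxifen, in 3 groups of 2 libraries (shControl, shALDOA1 and shALDOA2). Per the labels' protocols, RNA was extracted with TRIzol and made into strand-specific mRNA libraries for DNBSEQ sequencing. The deposited values are whole-number counts of reads per annotated gene, not normalized, and per the submitters' processing notes HISAT2, SAMtools, featureCounts and DESeq2 were used with build GRCh38, with no versions or settings given. The target sites of the hairpins are not given either.

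Of 60659 gene rows read, 1 was left out because it was broken across lines. Gene IDs were matched to a table of names (60462 without regard to the version; 178 more were named from GENCODE 29), so that 42021 had a symbol, and biotypes came from GENCODE 29 (58384 IDs). All 735 entries of 33 gene lists were matched. The way of counting was tested on genes that lie wholly within exons of an expressed gene (at least 2 reads per exonic base of the host over the 6 libraries, contained gene at least 100 bases). All 49 such genes on the same strand had 0 counts, so reads over 2 genes of the same strand were counted for neither. All 60 on the opposite strand had 0 counts too. That would also follow from counting by strand in these strand-specific libraries, so the opposite strand was not settled.

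Counts were tested with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood F test (glmQLFit, glmQLFTest) with TMM scaling and filterByExpr, which kept 15142 genes (12323 protein-coding; 1350 with over 25% of their exonic bases shared with another gene). One fit of all 6 libraries gave the contrasts, namely the mean of both hairpins against shControl, each hairpin against shControl, and shALDOA2 against shALDOA1. Benjamini-Hochberg adjusted p values under 0.05 were called changed, and this holds for "rose" and "fell" in the text. CPM was computed here from the counts with TMM effective library sizes. TMM factors lay between 0.962 and 1.04, the common biological coefficient of variation was 5.77%, mitochondrial genes held 4.06% to 4.66% and the top 10 genes 7.30% to 8.16% of the counts, and 23802 to 24418 genes had a count. Replicates differed beyond sampling noise, with a chi-square per gene of 2.56 between the control libraries, 4.94 within shALDOA1 and 4.70 within shALDOA2 (genes with at least 20 counts in both libraries together).

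Gene lists were fixed before the data were examined and tested with camera (limma 3.58.1, preset inter-gene correlation 0.01, at least 3 tested genes), which asks whether the genes of a list rank apart from all other genes, adjusted over the 31 lists tested in each contrast. Camera was rerun with the correlation estimated for each list, and fry was run beside it, which tests whether the genes of a list move on balance in 1 direction and does not compare them with other genes. The rerun of camera also has fewer degrees of freedom, those left by 6 libraries in 3 groups. A call lost there therefore need not come from correlation. For hypoxia genes in the mean contrast the estimated correlation was -0.046, below the preset 0.01. Camera's unadjusted p still went from 1.33e-04 to 0.0249. The genes to name were fixed by rule at the same time as the lists. They were ALDOA, ALDOB, ALDOC, ESR1 and PGR, the 10 protein-coding genes with the largest increase and the 10 with the largest decrease in the mean contrast (mean CPM at least 1, past the test the same way with each hairpin), up to 4 genes per list with the smallest adjusted p, and the 5 largest differences each way between the hairpins. For overlap and correlation of the hairpins, 30 sets of counts without any effect were simulated from the means, dispersions and library sizes.

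After the trend with base composition was seen, a correction was added. For each library the log2 deviation from the mean of libraries (0.5 added to counts) was fitted by loess (span 0.4, degree 2) on the GC content of the longest GENCODE 29 transcript and on the log2 exonic length, for the 14998 genes (99.0%) with a GC value, and the fit entered edgeR as offsets. This removes any real change that follows GC content as well. Corrected values are named as such, and all others are as counted. Matched random lists (10000) had the same GC content and expression as the list tested, but were not matched on length.

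Scripts were tested on simulated data with 200 changed genes. In the mean contrast, of 14900 genes tested, 57.6% of the genes changed by log2 0.5 and 85.9% of those changed by log2 1 were recovered, with 8 unchanged genes called. With a GC trend of 0.5 log2 per 10 points added and corrected (14743 genes) 55.1% and 77.7% were recovered with 11 unchanged genes called, and without correction (14880 genes) 8256 unchanged genes were called.

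Alternatives planned were RLE and upper-quartile scaling, no filter or CPM of at least 1 in 2 libraries, DESeq2 1.42.0 (Wald test), replicate number as a block, each library left out in turn, adjusted p under 0.01, a 2-fold minimum, only the 4 libraries compared, the hairpins as 1 group, ALDOA summed with the gene that overlaps it, genes with mean CPM of at least 10, and the list tests above. Chosen after seeing the data were the GC and length correction, leaving out genes with over 25% shared bases, leaving out mitochondrial genes before scaling, and DESeq2 without its filter on mean count. Tables and figures were made with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.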

Results

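The transcriptome of MCF7-TAMR cells was measured after knockdown of ALDOA, which encodes the glycolytic enzyme aldolase A. MCF7 is an oestrogen receptor positive line of human breast cancer, and MCF7-TAMR is a derivative that resists tamoxifen, a drug that competes with oestrogen for its receptor. Cells grew with 1 µM tamoxifen in all groups. Polyadenylated RNA was sequenced from 6 libraries in 3 groups of 2, namely a control hairpin (shControl) and 2 hairpins against ALDOA (shALDOA1 and shALDOA2). The deposited counts held between 12978632 and 14586930 reads assigned to genes per library. These were 14532034 and 12978632 with shControl, 13710858 and 14062066 with shALDOA1, and 13932135 and 14586930 with shALDOA2. The labels do not say whether the replicates were separate cultures, so the p-values measure only the spread between these libraries, which may be technical. The series concerns alternative splicing of ALDOA and tamoxifen resistance, and counts per gene do not tell isoforms apart.

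ALDOA was lower in each of the 4 knockdown libraries than in either control library. The deposited counts of ALDOA (ENSG00000149925.22, GRCh38 chromosome 16, 30064164 to 30070457, plus strand) were 666 and 583 with shControl, 279 and 265 with shALDOA1, and 283 and 323 with shALDOA2. The level was 44.2 ± 1.20 CPM (counts scaled to library size; SD, n = 2) with shControl, 20.2 ± 1.39 with shALDOA1 and 21.3 ± 1.15 with shALDOA2. Thus 45.7% and 48.2% of the control level as counted were left. The log2 fold change was -1.13 with shALDOA1 and -1.05 with shALDOA2, and -1.09 (SE 0.0735, adjusted p = 2.19e-10) for the mean of both. The hairpins did not differ detectably from each other (log2 difference 0.08, SE 0.0951, adjusted p = 0.777). Of the 3829 exonic bases of ALDOA, 2083 (54.4%) lie under another annotated gene, including 1254 of its 1350 coding bases. Reads that touched 2 genes of the same strand were counted for neither, and for genes of opposite strands this was not settled. The count therefore comes mostly from the remaining 1746 bases, or from 2184 if only the gene on the same strand takes reads away. It understates the amount of ALDOA mRNA. Of the 1746 bases, 984 lie in a continuous run and only 96 are coding. The percentages left and the fold changes of ALDOA therefore hold for the counted part. The size of the knockdown of the whole ALDOA mRNA was not measured and may differ. The overlapping gene on the same strand, ENSG00000285043.2 (chromosome 16, 30053090 to 30070420), had 41 and 42 counts with shControl, 32 and 34 with shALDOA1, and 27 and 37 with shALDOA2. The sum of both genes gave a log2 fold change of -1.03.

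The other aldolases and the receptors were counted too. ALDOC, the aldolase of brain (ENSG00000109107.14, chromosome 17, 28573115 to 28576948), fell from 33.6 ± 0.349 CPM (SD, n = 2) with shControl to 22.9 ± 0.930 with shALDOA1 and 20.9 ± 1.47 with shALDOA2 (log2 fold change of the mean -0.62, SE 0.0762, adjusted p = 5.51e-07). ESR1, the oestrogen receptor alpha gene (ENSG00000091831.24, chromosome 6, 151656691 to 152129619), fell from 240 ± 4.57 CPM to 161 ± 7.26 and 165 ± 9.50 (log2 fold change -0.56, SE 0.0563, adjusted p = 4.04e-08). After a correction for GC content and length the change was -0.13 (adjusted p = 0.0633) and no longer passed. ALDOB, the aldolase of liver, had 1 count in 1 shControl and in 1 shALDOA2 library and 0 in the others. PGR, the progesterone receptor gene, had between 0 and 2 counts per library, and neither gene was tested.

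**Figure D1:**
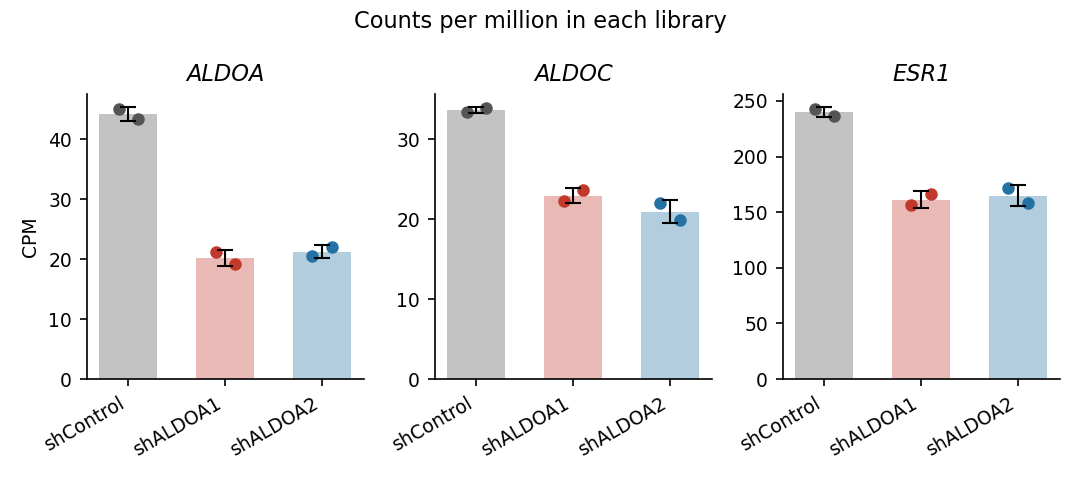
CPM of ALDOA, ALDOC and ESR1 (vertical axes from 0) in the 2 libraries of each group (points), with group means (bars) and SDs (whiskers). ALDOA stood at 44.2 with shControl against 20.2 and 21.3 with the hairpins, ALDOC at 33.6 against 22.9 and 20.9, and ESR1 at 240 against 161 and 165.

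The first comparison asked which genes changed in ALDOA knockdown cells in the mean of both hairpins, which a change with 1 hairpin alone can also move. By camera's test, lists of mitosis, hypoxia response and splicing genes were lower than with shControl, and lists of ribosomal protein and respiratory chain genes were higher. None of these list calls held with an estimated correlation (adjusted p = 0.590, 0.590, 0.590, 0.777 and 0.872). With so few libraries that rerun has little power, so it does not show these calls to be false. The splicing list was also not past camera's test after a correction for GC content and length (median 0.029, adjusted p = 0.980). Changes were broad and mostly small. Of 15142 genes tested, 8585 changed in the mean of both hairpins, 4151 upwards and 4434 downwards, with a median absolute log2 fold change of 0.48, and 526 changed 2-fold or more (268 up, 258 down). The change followed base composition. Across 14998 genes, Spearman's rho between the fold change and the GC content of the longest transcript was 0.663, with a median log2 fold change of -0.47 in the lowest of 10 equal GC classes and 0.47 in the highest. Between replicates rho was 0.003 for the 2 control libraries, 0.017 within shALDOA1 and -0.308 within shALDOA2 (genes are not independent replicates). For shALDOA2 against shALDOA1 it was 0.273. A GC trend thus also arose between libraries of the same hairpin. Its medians within shALDOA2 were smaller, at 0.097 in the lowest GC class and -0.098 in the highest. The fold change also followed exonic length, with a rho of -0.266. Between replicates this rho was 0.056 with shControl, 0.212 with shALDOA1 and 0.100 with shALDOA2. After a correction for both GC content and length, called the GC correction below, 5968 genes changed (3092 up, 2876 down). Of these, 3994 genes had the same call and direction in both fits and 388 were called in opposite directions.

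**Figure D2:**
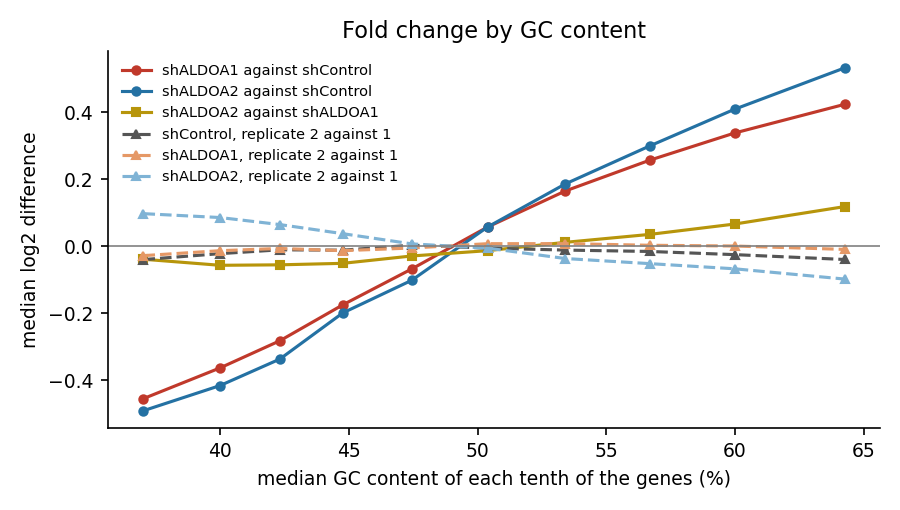
Median log2 difference (vertical axis) of the genes in each of 10 equal GC classes, at the median GC content of the class in percent (horizontal axis). Both comparisons with shControl (circles) climb with GC content, to 0.42 with shALDOA1 and 0.53 with shALDOA2, while the difference between hairpins (squares) and the replicate pairs (triangles, dashed) stay between -0.10 and 0.12.

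Several of the largest changes were the same in size with each hairpin. NEK7, a mitotic kinase that also takes part in the NLRP3 inflammasome (ENSG00000151414.15, chromosome 1, 198156994 to 198322420), fell from 62.1 ± 0.499 CPM (SD, n = 2) to 17.4 ± 1.90 with shALDOA1 and 17.4 ± 1.04 with shALDOA2 (log2 fold change -1.83, SE 0.0730, adjusted p = 3.19e-13). COQ10B, which binds coenzyme Q (ENSG00000115520.8, chromosome 2, 197453423 to 197475308), fell from 48.8 ± 4.44 to 16.8 ± 0.0772 and 16.9 ± 0.176 CPM (log2 fold change -1.54). KLHL11 (log2 fold change -2.20) and MATN3, a protein of the extracellular matrix (-1.97), also fell. Increases from low levels were seen for STMN4, a regulator of microtubules, from 0.389 ± 0.0241 to 2.45 ± 0.130 and 2.64 ± 0.254 CPM (log2 fold change 2.68). The serpin gene SERPINB5 rose from 0.851 ± 0.0570 to 2.26 ± 0.0835 and 3.44 ± 0.0625 CPM (1.71). ACTL8, an actin-like gene of the testis, rose from 4.55 ± 0.547 to 14.9 ± 0.406 and 16.1 ± 1.43 CPM (log2 fold change 1.76), and TMEM130 (1.66), CEL (1.62) and SYP (1.62) rose too. So did IRF7 (1.65), but its replicates lay apart. It stood at 1.15 and 0.520 CPM with shControl, 3.80 and 1.81 with shALDOA1 and 4.05 and 1.16 with shALDOA2. MRM1 rose by a log2 fold change of 3.83, but mostly with shALDOA2 (0.0710 ± 0.00475, 0.331 ± 0.147 and 3.74 ± 0.744 CPM).

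Other large changes rested on single libraries. Of the 10 largest increases 2, and of the 10 largest decreases 5, were at least 4-fold apart between replicates of 1 group. CUTA stood at 2.5 and 4.01 CPM with shControl, 87.3 and 11.5 with shALDOA1 and 3.76 and 87.9 with shALDOA2. Its log2 fold change of 3.88 was 2.07 without shALDOA2 replicate 2. ARHGAP27 (2.07) was at 1.27 without shALDOA1 replicate 2, and IRF7 at 1.08 without shALDOA2 replicate 1 and at 1.14 (adjusted p = 0.0605) after the GC correction. Without shControl replicate 1 the direction turned for NTAN1 (from -2.90 to 0.87), VARS1 (from -1.99 to 2.46), NOMO3 (from -1.52 to 0.08) and NOMO1 (from -1.47 to 0.17). Without shControl replicate 2 it turned for SPATC1L (from -2.52 to 0.55). INTS3 fell by 1.59 on the log2 scale. DESeq2's Wald test did not call ARHGAP27, INTS3, NTAN1, SPATC1L, VARS1, NOMO3 or NOMO1.

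Both hairpins moved largely the same genes. Against shControl, 7532 genes changed with shALDOA1 (3668 up, 3864 down; 475 by 2-fold or more) and 8270 with shALDOA2 (4008 up, 4262 down; 660 by 2-fold or more). With each hairpin 6695 changed the same way, 3190 up and 3505 down, while 16 changed in opposite directions. Independent lists of these sizes would share 2058 (971 up, 1088 down), and 30 simulations of unchanged groups set against the same controls gave a mean of 1.80 and at most 5. Across tested genes, which are not independent replicates, the fold changes of the hairpins had a Pearson r of 0.842 and a Spearman rho of 0.876, against 0.506 and 0.459 in the simulations, and a covariance of 0.230 against 0.0279. The difference in covariance was 0.202. Split controls would leave 1 library per hairpin, so they were not split, and part of the excess of the overlap and of r may come from the shared controls. The simulated covariance holds the share that the spread between control libraries adds, so the difference in covariance does not include that share. A deviation common to both control libraries was not simulated and may be part of the difference. After the GC correction 3896 genes changed the same way with each hairpin, r was 0.770 and the covariance was 0.135. With shALDOA2 5309 genes changed after it. DESeq2 without its filter on mean count called 4808 genes with shALDOA1, 5449 with shALDOA2 and 4329 the same way with both, and with no filter on expression r was 0.550.

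As counted, the list of the late cell cycle had the lowest median among 31 gene lists tested. Of 24 genes of G2 and mitosis, 21 fell, 2 rose and 1 did not pass (median log2 fold change -0.58; camera adjusted p = 6.67e-10, adjusted p = 0.590 with an estimated correlation). The median was -0.30 after the GC correction, with 18 genes down. HMMR, a spindle protein, fell from 55.3 ± 1.95 CPM (SD, n = 2) to 24.7 ± 2.97 and 22.6 ± 3.78 (log2 fold change -1.22). Also down were NDC80 of the kinetochore, which fell by 0.97, KIF20A of the cleavage furrow by 0.87 and topoisomerase TOP2A by 0.84 on the log2 scale. The S phase list had 7 of 24 genes up, 10 down and 7 not past the test (camera adjusted p = 0.715; 8 up and 11 down adjusted over the list alone). After the correction 2 rose and 10 fell (median -0.10, adjusted p = 0.00949). CCNE2, cyclin E2, fell by 1.17, MCM4 by 0.52 and RRM1 by 0.52, while E2F1 rose by 0.57, to 0.13 after the correction (adjusted p = 0.0779). Of 16 replication-dependent histone genes 7 fell and 9 did not pass (median -0.22, camera adjusted p = 0.447), among them H2AC11 (-1.03), H2BC4 (-0.83), H2AC6 (-0.48) and H2BC21 (-0.40). After the correction 9 fell and 0 rose (median -0.40, adjusted p = 0.00194), so that this median lay below that of G2 and mitosis. Only polyadenylated RNA was sequenced, so these values do not speak for histone mRNA without a poly(A) tail. Corrected changes were smaller by over 1.5 times for HMMR (-0.80), NDC80 (-0.63), TOP2A (-0.39), CCNE2 (-0.72) and RRM1 (-0.25).

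Splicing regulators and hypoxia genes were lower as well. Of 38 splicing regulators 25 fell, 1 rose and 12 did not pass (median -0.31; camera adjusted p = 4.79e-05, adjusted p = 0.590 with an estimated correlation). This list has a low GC content (median 40.9%), and after the GC correction its median was 0.029 with 8 genes up and 9 down (adjusted p = 0.980). SF3B1, a core part of the U2 snRNP, fell from 443 ± 3.19 to 267 ± 11.1 and 228 ± 13.7 CPM (SD, n = 2; log2 fold change -0.85, -0.44 after the correction). MBNL2 fell by 0.97, MBNL1 by 0.63 and HNRNPF by 0.60 on the log2 scale. Of 21 hypoxia response genes 12 fell, 0 rose and 9 did not pass (median -0.47; camera adjusted p = 0.00103, adjusted p = 0.590 with an estimated correlation). Their median was -0.26 after the correction. The mitophagy receptor BNIP3 fell from 213 ± 1.58 to 114 ± 1.15 and 108 ± 4.18 CPM (log2 fold change -0.95). Its relative BNIP3L fell by 0.64, the pyruvate dehydrogenase kinase PDK1 by 1.00 and the histone demethylase KDM3A by 0.66. The correction left MBNL2 (-0.50), MBNL1 (-0.21), PDK1 (-0.47), KDM3A (-0.15) and BNIP3L (-0.24).

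Ribosomal protein genes and nuclear-encoded genes of oxidative phosphorylation were higher by camera's test. Of 36 ribosomal protein genes 30 rose, 1 fell and 5 did not pass (median 0.33; camera adjusted p = 2.33e-08, adjusted p = 0.777 with an estimated correlation). Their median was 0.30 after the GC correction. RPS5 rose from 1216 ± 38.5 to 2023 ± 96.9 and 1888 ± 37.6 CPM (SD, n = 2; log2 fold change 0.69). Increases were also seen for RPL13, which rose by 0.63, RPSA by 0.58 and RPS9 by 1.15. Of 45 nuclear-encoded genes of oxidative phosphorylation 26 rose, 7 fell and 12 did not pass (median 0.21; camera adjusted p = 0.00484, adjusted p = 0.872 with an estimated correlation). Their median was 0.19 after the correction. The complex I genes NDUFV1 and NDUFB7 rose by 0.80 and 0.67 and the ATP synthase gene ATP5F1D by 0.71, whereas ATP5F1B, the catalytic subunit of the same enzyme, fell by 0.66. Of 13 mitochondrially encoded genes 5 rose, 2 fell and 6 did not pass (camera adjusted p = 0.639; 4 up and 2 down adjusted over the list alone). MT-ND1 (0.39), MT-ND3 (0.38) and MT-ND2 (0.27) rose and MT-ND4L (-0.49) fell. DESeq2's test did not call MT-ND1 or MT-ND2, and MT-ND2 was at 0.17 without shALDOA2 replicate 2. The median of the mitochondrially encoded list was 0.15 as counted and 0.090 after the correction. Although the medians of the other lists here moved little, the correction left NDUFV1 (0.44), NDUFB7 (0.19), ATP5F1D (0.24), RPL13 (0.35) and MT-ND3 (0.21).

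**Figure D3:**
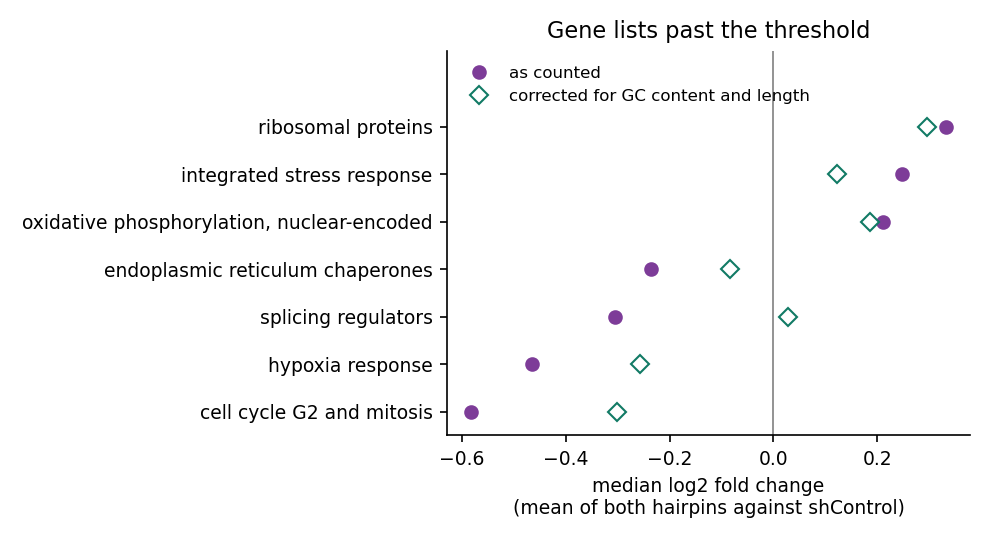
Median log2 fold change (horizontal axis, mean of both hairpins against shControl) of the 7 gene lists past camera's threshold, as counted (filled circles) and after the correction for GC content and length (open diamonds). Genes of G2 and mitosis stood at -0.58 and -0.30, splicing regulators at -0.31 and 0.029, and ribosomal proteins at 0.33 and 0.30.

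Glycolysis, the pathway of the targeted enzyme, did not move as a group. Of its 23 other genes 9 rose, 6 fell and 8 did not pass (median 0.017, camera adjusted p = 0.712). After the GC correction 7 of its genes rose and 9 fell (median -0.071, camera adjusted p = 0.351). Its phosphofructokinases rose, PFKL from 416 ± 11.8 to 705 ± 5.37 and 707 ± 2.37 CPM (SD, n = 2; log2 fold change 0.76, 0.33 after the GC correction) and PFKM by 0.57. Hexokinase HK2 and phosphoglycerate kinase PGK1 fell by 0.62 and 0.57 on the log2 scale. Of 9 genes of the pentose phosphate pathway 5 rose, 1 fell and 3 did not pass (camera adjusted p = 0.432; 6 up and 2 down adjusted over the list alone). PGLS rose by 0.57 and RPE fell by 0.52, and the correction brought these to 0.14 (adjusted p = 0.0885) and -0.13 (adjusted p = 0.0630). PGD rose by 0.33, and G6PD, the first enzyme of the pathway, rose by 0.27 as counted but turned to -0.20 (adjusted p = 0.00171) after the correction. Of 22 genes of the TCA cycle 11 rose, 10 fell and 1 did not pass (camera adjusted p = 0.897), with PC (0.65) and ACO2 (0.56) up and SUCLA2 (-0.79) and DLD (-0.73) down. Smaller after the correction were also PGK1 (-0.28), PGD (0.17), PC (0.27), SUCLA2 (-0.40) and DLD (-0.30).

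Oestrogen receptor targets and luminal genes moved both ways. Of 28 receptor targets 5 rose, 11 fell and 12 did not pass (median -0.08, camera adjusted p = 0.639), and after the GC correction 3 rose and 14 fell (median -0.20, adjusted p = 3.42e-04). The unfolded protein response factor XBP1 fell from 927 ± 22 to 614 ± 2.44 and 530 ± 10.1 CPM (SD, n = 2; log2 fold change -0.70). Carbonic anhydrase CA12 fell by 0.62 and cyclin D1 (CCND1) by 0.56, while ABCA3 rose by 0.50 and the cathepsin CTSD by 0.67. Of 18 luminal identity genes 7 rose, 5 fell and 6 did not pass (camera adjusted p = 0.875). After the correction 2 luminal genes rose and 8 fell (median -0.12, camera adjusted p = 0.133). The secreted TFF3 rose by 0.71, EPCAM fell by 0.36, and SPDEF rose by 0.36 as counted but was at -0.10 after the correction. Of 23 growth factor receptor and MAPK feedback genes 2 rose, 7 fell and 14 did not pass (camera adjusted p = 0.715; 1 up and 7 down adjusted over the list alone). ERBB2 rose by 0.36, INSR and FGFR3 fell by 0.58 and 0.35, and MET fell by 0.30 but was at 0.04 after the correction. Of the other genes here, XBP1 (-0.43), CTSD (0.20), ABCA3 (0.14), TFF3 (0.42) and ERBB2 (0.16) were smaller after the correction and FGFR3 (-0.77) was larger.

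By camera's test, genes of the integrated stress response were higher and chaperone genes lower, but neither call held with an estimated correlation (adjusted p = 0.590 for each). Of 24 genes of the integrated stress response 12 rose, 4 fell and 8 did not pass (median 0.25; camera adjusted p = 0.0453, adjusted p = 0.590 with an estimated correlation). Its adjusted p was 0.619 after the GC correction, 0.0570 without shALDOA2 replicate 2 and 0.0933 without shControl replicate 2. NUPR1 rose from 23.9 ± 3.51 to 58.2 ± 13.2 and 50.2 ± 2.58 CPM (SD, n = 2; log2 fold change 1.17). ATF5 rose by 0.75, ATF4 by 0.61 and TRIB3 by 0.54. Of 19 endoplasmic reticulum chaperone genes 3 rose, 11 fell and 5 did not pass (median -0.24; camera adjusted p = 0.0297, adjusted p = 0.590 with an estimated correlation; 4 up and 11 down adjusted over the list alone). Calnexin (CANX) fell by 0.73, DNAJB9 by 0.98 and SEL1L by 0.59. This list was at an adjusted p of 0.0610 without genes that overlap others. Of 22 p53 targets 10 rose, 9 fell and 3 did not pass (camera adjusted p = 0.183; 11 up and 9 down adjusted over the list alone), with FDXR (1.16), TP53I3 (1.05), BBC3 (0.96) and BAX (0.70) up. Of 21 NRF2 targets 3 rose, 10 fell and 8 did not pass (median -0.06, camera adjusted p = 0.0536), and after the GC correction 2 rose and 12 fell (median -0.19, adjusted p = 2.10e-04). Thioredoxin reductase TXNRD1 fell from 684 ± 11 to 336 ± 10.3 and 311 ± 13.4 CPM (log2 fold change -1.08). Haem oxygenase HMOX1 fell by 0.75, AKR1C2 by 0.68 and GCLM by 0.60, which was -0.13 (adjusted p = 0.116) after the correction. It also reduced ATF4 (0.31), ATF5 (0.36), TRIB3 (0.13), CANX (-0.36), SEL1L (-0.16), FDXR (0.73), TP53I3 (0.69), BBC3 (0.43), BAX (0.33) and AKR1C2 (-0.26).

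As counted, no other list passed camera's test in the mean of both hairpins, while 6 lists passed only after the GC correction, which was tested with the preset correlation alone. Among lipid genes, 8 of 22 genes of cholesterol synthesis rose and 11 fell (camera adjusted p = 0.855; 9 and 11 adjusted over the list alone), with PMVK (0.89), MVD (0.79) and MVK (0.74) up and the rate-limiting HMGCR (-0.64) down. In addition, 3 of 14 genes of fatty acid synthesis rose and 7 fell (camera adjusted p = 0.715), with SCD at -0.39 and ACSL3 at -0.56 (-0.08 after the GC correction). FASN and SREBF1 rose by 0.39 and 0.33 as counted and were at -0.07 and -0.08 after the correction. Of 29 interferon response genes 6 rose and 8 fell (camera adjusted p = 0.875). Of 13 inflammatory targets of NF-kB 2 rose and 2 fell (camera adjusted p = 0.766). These were NFKB2 (0.46) and RELB (0.73) up and NFKBIA (-0.28) and NFKBIZ (-0.29) down, of which NFKBIA alone stayed past the test after the correction. Of 11 genes of the epithelial-mesenchymal transition 4 rose and 0 fell (camera adjusted p = 0.639; 2 up adjusted over the list alone). These were TAGLN (0.75), MMP9 (0.57), TGFB1 (0.46) and FN1 (0.23), and the correction left TGFB1 at 0.0024, MMP9 at 0.13 and FN1 at 0.70. FN1 passed with 1 library left out only when that was shALDOA2 replicate 2, and without shControl replicate 1 its adjusted p was 0.306. MMP9 (adjusted p = 0.347) and NFKBIZ (adjusted p = 0.278) also missed the test without shControl replicate 1. Corrected values were PMVK (0.49), MVD (0.33), MVK (0.43), HMGCR (-0.26), NFKB2 (0.03), RELB (0.24), NFKBIZ (-0.13), NFKBIA (-0.46) and TAGLN (0.47).

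Of 28 actin cytoskeleton genes 9 rose and 8 fell (camera adjusted p = 0.715), with TPM4 (0.68), FLNA (0.64) and TMSB10 (0.57) up and WASL (-0.56) down. Of 14 YAP and SRF targets 3 rose and 7 fell (camera adjusted p = 0.715; 4 and 7 adjusted over the list alone), with IER2 (0.61) up and LATS2 (-0.69), AMOTL2 (-0.58) and TEAD1 (-0.58) down. After the correction 1 rose and 7 fell (median -0.25, adjusted p = 0.00359), and the call of TEAD1 ended (-0.16, adjusted p = 0.0922). Of 26 lysosome and autophagy genes 10 rose and 5 fell (camera adjusted p = 0.748), with GAA (0.77) and HEXA (0.74) up and the proton pump gene ATP6V1A (-0.95) down; LAMP2, at -0.55, was at -0.09 after the correction. Of 22 apoptosis regulators 6 rose and 8 fell (camera adjusted p = 0.875), with BAD (0.66) up and MCL1 (-0.41) down. Of 11 stemness genes 1 rose and 6 fell (median -0.39, camera adjusted p = 0.134), with JAG1 (-1.38), BMI1 (-0.73) and KLF4 (-0.42) down. After the correction 0 rose and 8 fell (median -0.32, adjusted p = 0.00110). Of 9 drug efflux transporters 2 rose and 3 fell (camera adjusted p = 0.904), with ABCG2 (-0.81) and ABCC5 (-0.32) down and ABCC10 (0.59) and ABCA3 (0.50) up. In this contrast, counts adjusted over the list alone equalled those over all genes for the lists where they are not given. Of the actin, YAP and SRF, lysosome, apoptosis, stemness and efflux genes, the correction reduced FLNA (0.35), TMSB10 (0.25), WASL (-0.18), IER2 (0.18), ATP6V1A (-0.56), GAA (0.30), BAD (0.18), MCL1 (-0.20), BMI1 (-0.32), ABCG2 (-0.43), ABCC10 (0.29), ABCA3 (0.14) and ABCC5 (-0.11) and enlarged TPM4 (1.06), HEXA (1.16) and KLF4 (-0.65). The call of ABCC5 ended with it (adjusted p = 0.0601). Markers of other cell types came last. None of the 6 tested basal or myoepithelial markers changed (0 up, 0 down; camera adjusted p = 0.875), and 1 of 3 endothelial markers fell (camera adjusted p = 0.897). The fibroblast and leukocyte lists had 2 tested genes each, too few for the list test, of which 2 and 1 rose, and 0 of either after the correction. COL1A1 stood at 11 ± 0.516 CPM (SD, n = 2) with shControl and 12.7 ± 0.00497 and 15.3 ± 0.706 with the hairpins (log2 fold change 0.34, -0.0095 after the correction), COL3A1 at 0.929 ± 0.262, 1.49 ± 0.258 and 1.98 ± 0.575, and the leukocyte integrin ITGB2 at 3.11 ± 0.192, 4.84 ± 1.21 and 4.15 ± 0.363. The calls of COL3A1 and ITGB2 ended with the correction (adjusted p = 0.0563 and 0.528). For the TCA cycle, actin, apoptosis, drug efflux and basal lists the sign of the median (0.032, -0.0071, -0.056, 0.052 and -0.012) was opposite to the direction of camera, and none of these passed.

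Against shControl, 4 lists passed camera's test the same way with each hairpin, namely G2 and mitosis, splicing regulators, hypoxia and ribosomal proteins. The interferon list passed in opposite directions. For oxidative phosphorylation, the integrated stress response, chaperones and NRF2 targets only 1 of the 2 calls passed (adjusted p = 0.0764, 0.0931, 0.0516 and 0.178 in the other). The test between hairpins did not pass for the integrated stress response (adjusted p = 0.260) and chaperones (adjusted p = 0.153). It passed for oxidative phosphorylation (adjusted p = 2.04e-06, adjusted p = 0.717 with an estimated correlation) and NRF2 targets (adjusted p = 0.00419, adjusted p = 0.610 with an estimated correlation). After the GC correction oxidative phosphorylation and NRF2 targets passed with both hairpins (adjusted p = 0.00178 with shALDOA2 and 0.00339 with shALDOA1), and the integrated stress response passed with neither (adjusted p = 0.268 and 0.802). With shALDOA1, G2 and mitosis genes (21 of 24 down, median -0.63), splicing regulators (24 of 38 down, -0.30) and hypoxia genes (12 of 21 down, -0.45) fell. Ribosomal protein genes (32 of 36 up, 0.43), oxidative phosphorylation (27 of 45 up, 0.29), the integrated stress response (12 of 24 up, 0.27) and interferon response genes (17 of 29 up, 0.70) rose. Camera gave adjusted p between 8.58e-13 and 0.0137, and adjusted p between 0.437 and 0.657 with an estimated correlation. With shALDOA2, G2 and mitosis genes (19 of 24 down, -0.54), splicing regulators (23 of 38 down, -0.33), hypoxia genes (11 of 21 down, -0.48), chaperones (11 of 19 down, -0.31), NRF2 targets (10 of 21 down, -0.15) and interferon response genes (16 of 29 down, -0.46) fell and ribosomal protein genes (22 of 36 up, 0.24) rose. Here camera gave adjusted p between 3.14e-08 and 0.0181, and adjusted p between 0.543 and 0.912 with an estimated correlation. Adjusted over the list alone, 34 ribosomal protein and 28 oxidative phosphorylation genes and 13 genes of the integrated stress response rose and 25 splicing regulators fell with shALDOA1, and 20 G2 and mitosis genes and 24 splicing regulators fell with shALDOA2. The correction left splicing regulators at 0.037 with shALDOA1 and 0.012 with shALDOA2.

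The last comparison asked where the hairpins differed from each other. Interferon response genes formed the clearest difference. By camera's test this list was higher with shALDOA1 than with shControl and lower with shALDOA2, but neither of these calls held with an estimated correlation (adjusted p = 0.437 and 0.543). Of 29 genes tested 18 were lower with shALDOA2 than with shALDOA1, 0 were higher and 11 did not pass (24 lower adjusted over the list alone), with a median log2 difference of -0.97 (camera adjusted p = 2.42e-135, adjusted p = 0.0103 with an estimated correlation) and of -0.94 after the GC correction. IFI6, an interferon-induced mitochondrial protein, stood at 127 ± 0.316 CPM (SD, n = 2) with shControl, 297 ± 31.5 with shALDOA1 and 120 ± 0.474 with shALDOA2 (log2 difference -1.31, SE 0.0719, adjusted p = 1.30e-10). OAS2, a sensor of double-stranded RNA, stood at 3.48 ± 0.433, 7.74 ± 0.954 and 1.40 ± 0.0438 (log2 difference -2.45, adjusted p = 4.78e-07), and IFIT3 at 3.79 ± 0.948, 6.90 ± 0.299 and 1.72 ± 0.118 (-2.00, adjusted p = 1.22e-05). STAT1, the transcription factor of the response, was below shControl with both, at 188 ± 2.5, 158 ± 8.52 and 94.6 ± 12.9 CPM (log2 difference -0.74). SAMD9 stood at 10.4 ± 0.353, 10.1 ± 0.456 and 3.27 ± 0.279 (-1.63), and BST2 did not pass (-0.25, adjusted p = 0.143).

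**Figure D4:**
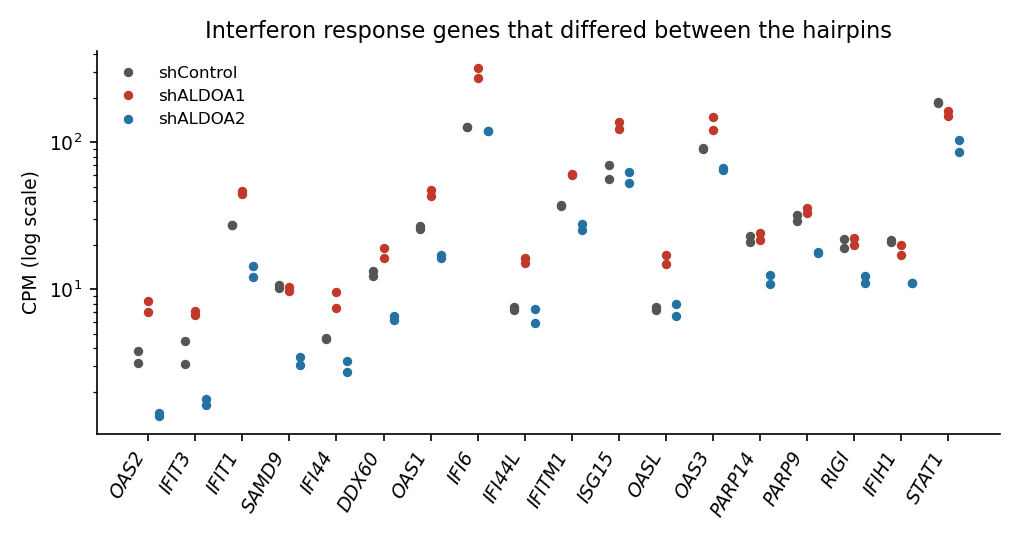
CPM (vertical axis, log scale) in each of the 6 libraries (points) of the 18 interferon response genes that differed between the hairpins, ordered by the log2 difference. The shALDOA2 points lie below the shALDOA1 points in all 18, with IFI6 near 297 with shALDOA1 and 120 with shALDOA2.

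The other differences were in single genes and small shifts of lists. In all, 113 genes differed between the hairpins, 40 higher and 73 lower with shALDOA2, 37 of them by 2-fold or more. The number was 214 without shALDOA1 replicate 2 and 71 without shALDOA2 replicate 1. After the GC correction 70 differed, 15 higher and 55 lower, and the number was 337 with no filter and 58 with DESeq2 without its filter on mean count. The largest difference was in KIFC1, a mitotic kinesin (ENSG00000237649.8, chromosome 6, 33391823 to 33409896), at 0.287 ± 0.119 CPM (SD, n = 2) with shControl, 13.4 ± 1.02 with shALDOA1 and 0.424 ± 0.116 with shALDOA2 (log2 difference -4.96, SE 0.259, adjusted p = 1.29e-10). Higher with shALDOA2 were GGNBP2 (log2 difference 4.36, SE 0.426, adjusted p = 1.71e-06; 0.295 ± 0.0953 against 6.25 ± 0.0507 CPM), MRM1 (3.45) and SYNRG (2.36), 3 genes of chromosome 17 between 36544912 and 37609472, as well as PARN (3.81) and NKD2 (1.71). YWHAE (-3.06) and EEF1D (-1.84) were lower, but these rested on shALDOA1 replicate 2, without which the differences were -0.41 and -0.07. Any 1 knockdown library left out ended the call of PARN, as did shALDOA1 replicate 2 or shALDOA2 replicate 1 for NKD2 (adjusted p = 0.0901 and 0.223) and shALDOA2 replicate 2 for SYNRG (adjusted p = 0.0628). Ribosomal protein genes (median -0.15, 1 of 36 lower, 8 adjusted over the list alone), oxidative phosphorylation (-0.11, 1 of 45 lower, 5 adjusted over the list alone), NRF2 targets (-0.12, 1 of 21 lower, 2 adjusted over the list alone) and histones (-0.22, 1 of 16 lower, 2 adjusted over the list alone) were slightly lower with shALDOA2 by camera (adjusted p between 5.14e-12 and 0.0428). None passed with an estimated correlation (adjusted p = 0.717, 0.717, 0.610 and 0.647). After the GC correction, tested with the preset correlation, 4 of the 5 list calls between the hairpins stayed. The histone list lost its call (adjusted p = 0.119), as it did with replicate number as a block. With the correction 3 more lists passed camera. G2 and mitosis genes were higher with shALDOA2 (adjusted p = 0.0283), and NF-kB targets (adjusted p = 0.0280) and actin genes (adjusted p = 0.0239) lower. Without shALDOA1 replicate 1 oxidative phosphorylation, NRF2 targets and histones no longer passed camera (adjusted p = 0.138, 0.188 and 0.188).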

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

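Each result here differed between the hairpins by a test of shALDOA2 against shALDOA1, which is why it was looked at again. All tests of explanations were chosen after the results were seen. The genes were GGNBP2 (log2 difference 4.36), PARN (3.81), MRM1 (3.45), SYNRG (2.36), NKD2 (1.71), KIFC1 (-4.96), YWHAE (-3.06), OAS2 (-2.45), IFIT3 (-2.00) and EEF1D (-1.84). The lists were interferon response (median -0.97), histones (-0.22), ribosomal proteins (-0.15), NRF2 targets (-0.12) and oxidative phosphorylation (-0.11).

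Interferon response genes lay above shControl with shALDOA1 (median log2 fold change 0.70; 17 genes up, 1 down) and below it with shALDOA2 (-0.46; 2 up, 16 down), though neither list call holds with an estimated correlation (adjusted p = 0.437 and 0.543). OAS2, IFIT3, IFIT1, IFI44, DDX60, OAS1, IFITM1 and OAS3 passed up with shALDOA1 and down with shALDOA2. Other genes passed with 1 hairpin alone, as IFI6 and SAMD9, or with neither. STAT1, BST2 and IRF7 moved the same way with both. ALDOA differed between the hairpins by only 0.08 (SE 0.0951). For the genes that moved in opposite directions, this argues against a different degree of loss of ALDOA as counted here. Of its 1350 coding bases 1254 lie under another gene, so a different loss of the whole mRNA or of an isoform stays open. The difference stayed at -0.94 after the GC correction, and its smallest size without 1 of the knockdown libraries was -0.87 (highest adjusted p 4.18e-79), which speaks against base composition or a single library. Sensing of the RNA of a hairpin, or another target of it, cannot be told apart from an effect of how each hairpin lowers ALDOA isoforms.

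The changes in the mean of both hairpins were set against base composition. With the GC correction 3994 of 8585 genes kept call and direction, so the trend as fitted does not account for all of them. Any trend that the GC content of the longest transcript and the length do not capture would remain after it. Splicing regulators had a median of -0.31 as counted, at percentile 59.8 of random lists matched on GC content and expression, and 0.029 after the correction, which fits the trend as the source of their fall, whatever lies behind that trend. The median of G2 and mitosis genes as counted, -0.58, lay below all matched random lists (percentile 0). It shrank to -0.30 after the correction, with 18 of 24 genes still down and 0 up, so the trend as fitted is not the whole source. This list call does not hold with an estimated correlation (adjusted p = 0.590 as counted), which was not run after the correction. The knockdown libraries of the 2 hairpins lay at most 9.02 apart in chi-square per gene, against at least 36.0 between a control and a knockdown library, so an effect of ALDOA loss and a difference in preparation shared by the knockdown libraries cannot be told apart.

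Some genes jumped between replicates of 1 group. Of 13804 genes with mean CPM of at least 1, 47 were 4-fold or more apart in some pair. In 20 simulated sets, where each gene had the spread fitted for its level, the mean was 0.6 and the most 3. Counting error and that fitted spread do not explain the 47, but spread particular to a gene was not simulated. Of the 47 genes 25 lay within 1 Mb of another, against a mean of 3.24 and at most 14 in 1000 random draws. The 13 genes of the major histocompatibility complex region that were looked up had a median CPM of 0.247 against 18.9 for tested genes, with 0 counts for HLA-B and HLA-C in every library. Both values fit reads with more than 1 placement, as on alternate copies of a region, being dropped or assigned unevenly, and no biological explanation was tested. PARN, YWHAE and EEF1D are among these genes, and GGNBP2, MRM1, SYNRG and KIFC1 lie near others (DHRS11 between GGNBP2 and MRM1, PHF1 and CUTA beside KIFC1), so uneven placement stays open for their differences too. It also stays open for the rise of IRF7 with both hairpins, as IRF7 lies beside PHRF1 and HRAS, which jumped between replicates.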

How the results depend on the processing

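ALDOA kept its fall in all settings (log2 fold change between -1.30 and -1.03), and RLE or upper-quartile scaling changed no call of a named gene or list. The cause was not tested for any change below except the lower counts under stricter thresholds, which follow from their construction. A 2-fold minimum left 526 genes in the mean contrast, 475 with shALDOA1, 660 with shALDOA2, 37 between the hairpins and 256 with both hairpins, and an adjusted p under 0.01 left 49 between the hairpins. With no filter 337 genes differed between the hairpins, and the correlation of the hairpins was 0.550, against 0.945 over genes with mean CPM of at least 10. Among alternatives chosen after seeing the data, the GC correction gave 5309 genes with shALDOA2, 70 between the hairpins, 3896 with both and a correlation of 0.770, and it put 11, 11 and 13 lists past the test in the mean contrast, with shALDOA1 and with shALDOA2. It turned the splicing regulators to 0.029 in the mean contrast and 0.037 with shALDOA1, and turned G6PD (-0.20), SPDEF (-0.10), MET (0.041), FASN (-0.068), SREBF1 (-0.078) and COL1A1 (-0.0095). DESeq2 without its filter, which adjusts over 31638 genes, called 4808 genes with shALDOA1, 5449 with shALDOA2, 58 between the hairpins and 4329 with both. With its filter it gave no adjusted p to the 10 genes named between the hairpins. Without genes that overlap others 3 lists differed between the hairpins. With an estimated correlation 0, 0, 0 and 1 lists passed in the 4 contrasts, and with fry 19, 20, 16 and 1.

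With 1 library left out, where the lone library of a group is assumed to vary like the other groups, between 71 (without shALDOA2 replicate 1) and 214 genes (without shALDOA1 replicate 2) and between 2 (without shALDOA1 replicate 1) and 7 lists (without shALDOA1 replicate 2) differed between the hairpins, and the correlation of the hairpins lay between 0.733 (without shALDOA1 replicate 2) and 0.842. The mitochondrially encoded list ranged from -0.13 (without shALDOA2 replicate 2) to 0.15 (without shALDOA1 replicate 2) between the hairpins. NTAN1 ranged from -3.82 to 0.87, SPATC1L from -3.48 to 0.55, NOMO3 from -2.23 to 0.078 and NOMO1 from -2.20 to 0.17, each set by which control library was left out, and VARS1 from -3.12 (without shALDOA1 replicate 2) to 2.46 (without shControl replicate 1). Of 2579 settings of 153 named genes, calls were lost in 32 that left out a library, 23 of DESeq2 without its filter, 19 of the GC correction, 15 of DESeq2, 3 with the hairpins as 1 group and 1 with no filter. Of 1980 settings of lists, calls were lost in 25 with an estimated correlation, 9 that left out a library and 5 of fry. They were also lost in 4 of the GC correction and 3 without overlapping genes. Calls were gained in 35 of fry, 22 of the GC correction, 12 that left out a library and 9 with no filter. Settings that turned the sign were counted apart from all of these. For genes they were 6 of the GC correction and 5 that left out a library, and for lists 2 and 1. Some of these lost their call as well, among them COL1A1 and the splicing regulators after the correction.

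With the replicate block 241 genes differed between the hairpins, and the histone list no longer passed in that contrast (adjusted p = 0.0525); it changed no other call. Deviations of libraries with the same number had correlations of -0.011, -0.0032 and 0.0098 between groups, which shows no pairing by number. The mitochondrial share was higher in replicate 2 of each group (4.23% and 4.66% with shControl, 4.16% and 4.62% with shALDOA1, 4.06% and 4.63% with shALDOA2), so a step shared by libraries of the same number is not excluded. Depth limits calls of genes at low levels, such as ALDOB and PGR, which were not tested.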

Other observations

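Symbol families were looked at after the fixed lists. Of 149 families with at least 10 tested genes, 3 passed camera in the mean of both hairpins. The RPL family rose (32 of 49 genes up, 2 down, median log2 fold change 0.29, adjusted p = 5.66e-05), as did RPS (31 of 42 up, 5 down, 0.36, adjusted p = 5.66e-05). Both kept this after the GC correction (0.26 and 0.31). Families share only the letters that open the symbol, so RPS can also hold genes that are not ribosomal proteins. Families were tested with the preset correlation alone, and the fixed list of ribosomal proteins lost its call with an estimated correlation (adjusted p = 0.777). The ubiquitin-specific proteases of the USP family fell (29 of 48 down, 6 up, -0.27, adjusted p = 0.00790), but stood at -0.10 after the correction (adjusted p = 0.312). The NEK kinases (6 of 10 down, 1 up, -0.53), nucleoporins of the NUP family (14 of 23 down, 4 up, -0.36) and kinesins of the KIF family (16 of 32 down, 5 up, -0.28) were lower and the mitochondrial ribosomal MRPL family (28 of 47 up, 13 down, 0.20) higher without passing (adjusted p = 0.0587 for each). After the correction these stood at -0.25 for NEK, -0.09 for NUP, -0.13 for KIF and 0.15 for MRPL.

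Some genes that jumped between replicates were neighbours, and these were chosen after their values were seen. PARN, NOMO1, NTAN1, RRN3 and NOMO3 lie on chromosome 16 between 14435700 and 16300806, LY6E, GSDMD, NAPRT and EEF1D on chromosome 8 between 143017982 and 143599541, and PHF1 and CUTA on chromosome 6 between 33410399 and 33418317, next to KIFC1. DHRS11 (chromosome 17, 36591879 to 36600804), which differed 4.57-fold between replicates, lies between GGNBP2 and MRM1. HRAS and PHRF1 lie on chromosome 11 between 532242 and 612222, next to IRF7 (612553 to 615983). VARS1 and GBA1 differed most between replicates, 37.5-fold and 44.0-fold. The first principal component held 58.3% of the variance and parted knockdown from control libraries, and the second, with 13.7%, parted the hairpins.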
